A study of Homo sapiens with 16 samples.

How the data were processed

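RNA from cells of human breast tumours was measured after flow sorting with the ALDEFLUOR assay, which marks living cells by their aldehyde dehydrogenase activity. Sorted cells with that activity (ALDH+) gave 8 arrays and cells without it (ALDH-) gave 8 arrays. Per the labels' protocols, total RNA was extracted from frozen sorted cells, and 50 ng of it went through Affymetrix labelling with a repeated amplification cycle before hybridisation of the biotinylated cRNA. The values analysed here are the deposited log2 expression values, 1 per probe set and array, which the authors made with RMA, per the submitters' processing notes. RMA corrects the background, brings all arrays to 1 common distribution and summarises the probes of a probe set on the log2 scale. Its version, and the settings used with it, are not given in the sources used here. Because the distributions were made alike before deposit, a change in total RNA per cell leaves no trace in these values. Low signals are compressed towards the background, so a difference that starts or ends near the floor is understated.

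The table held 54675 probe sets on 16 arrays. The platform annotation paired 41097 probe sets with 1 gene, of which 41043 were matched in the RefSeq gene table, and 1801 with several genes. For 11721 probe sets no gene was listed, and 62 were controls. Another 67 probe sets of Y-linked genes and of 2 X-inactivation transcripts were left out because the samples came from people. Gene symbols were updated through the gene identifiers of the annotation. Where several probe sets named the same gene alone, the one with the highest mean over all arrays stood for it, which gave 19740 genes. Genes were tested where that mean reached the median of all probe-set means, a log2 value of 5.82, which left 13163 genes. Probe sets that name several genes were not named in the text. Signal intensities, detection calls and scan images were not used here, and the number of arrays limits the precision.

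The comparison was ALDH+ minus ALDH- over all 16 arrays, fitted with limma (version 3.58.1, R version 4.3.3) with lmFit and eBayes and no covariate. P-values were two-sided and adjusted by the Benjamini-Hochberg method, with a threshold of 0.05. Gene lists were tested with limma's camera at its preset inter-gene correlation of 0.01 and adjusted over all 30 lists. The estimated correlation and limma's fry, a test of whether a list's genes move on balance in 1 direction, were run as alternatives. A list score is the mean over a list's members of the log2 value minus that gene's mean over all arrays. Scores were compared between groups with a two-sided exact permutation test over all arrangements of 8 against 8 arrays and adjusted over the 30 lists.

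The 22 gene lists and 8 lists of cell type markers were fixed before the data were examined. They cover aldehyde dehydrogenases, retinoid handling, breast epithelial states, mesenchymal transition, the cell cycle, stem cell markers, the Notch, Wnt and Hedgehog pathways, metabolism, antioxidant genes, ABC transporters, interferon and inflammatory genes, stress responses and ribosomal proteins. The marker lists cover fibroblasts, endothelium, T and NK cells, B and plasma cells, macrophages, mast cells, erythrocytes and adipocytes. The design, the comparisons and the alternatives were fixed at the same point, except those said below to be added later. The rule for named genes took the 12 largest rises and the 12 largest falls among the genes past the threshold whose sign held with array batch as a block. It always took ALDH1A1, ALDH1A3, CD44, CD24, EPCAM, ITGA6, CDH1, VIM, ESR1, ERBB2, KIT and MKI67. From each list it took up to 4 members with the smallest p.

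The description field of each sample holds a name whose first part is shared by some arrays. Arrays sharing that part were treated as 1 batch, written A to F here. Batches C, D and E held both groups, with 6 ALDH+ and 4 ALDH- arrays between them. Batch B held 4 ALDH- arrays only, and batches A and F held 1 ALDH+ array each. Batch was fitted as a fixed block and as a random block, and differences were also computed within batches C, D and E. As a fixed block, batch absorbs the arrays of A, B and F, so the group difference there comes from C, D and E alone.

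The other alternatives were no filter and a filter at the 75th percentile, quantile normalization and median centring of the deposited values, the mean of a gene's probe sets, every probe set on its own, a trended and robust variance prior, array weights, the replicate number as a block, the RNA quality measure as a covariate, other thresholds, and each array left out in turn. A fit with the T and NK cell score as covariate and a fit without 2 arrays that stood apart on the principal components were added after the data were seen. RNA quality was read from the control probe sets of ACTB and GAPDH as log2 signal at the 3 prime end minus that at the 5 prime end.

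The fit was tested on simulated data for the comparison of ALDH+ with ALDH-, with 13163 genes carrying the spread of the real arrays and 200 genes changed by a known amount. It recovered 31% of genes changed by 1 on the log2 scale, 75% of those changed by 2, 89.5% of those changed by 3 and 96.5% of those changed by 4. A change of 2-fold was therefore missed more often than found in these simulated data. The simulated genes were drawn independently of each other and without batch, unlike the real arrays, so recovery there can differ.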

Results

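Expression was measured in cells of human breast tumours that had been sorted by aldehyde dehydrogenase activity. The sort gave 8 ALDH+ and 8 ALDH- arrays, each with a value for 54675 probe sets. Deposited log2 values ran from 2.83 to 15.1, with array medians between 5.69 and 5.81. Pairs of arrays correlated at 0.777 to 0.970 across probe sets. The first principal component held 32.8% of the variance and differed between the groups (two-sided exact permutation p = 0.00606). The labels call the arrays biological replicates without saying that each came from a separate tumour, so p-values measure the spread between these samples. The design asks how the profile of ALDH+ cells differs from that of ALDH- cells.

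Lymphocyte genes were far lower in ALDH+ cells. LCK, the kinase that starts T cell receptor signalling, averaged 5.53 ± 0.42 in ALDH+ and 10.79 ± 2.16 in ALDH- arrays (SD, n = 8 each), a log2 difference of -5.26 (SE 0.73, limma adjusted p = 0.00429). GNLY, a cytolytic granule protein, fell by 5.37 on the log2 scale and the granule proteases GZMA, GZMB and GZMK differed by -5.15, -5.03 and -4.53. CD2, an adhesion receptor of T and NK cells, fell by 5.00, and TRBC1, a constant segment of the T cell receptor, differed by -5.11. IFNG, the interferon of T and NK cells, fell by 4.64, the T cell inhibitory receptor CTLA4 by 4.74 and NKG7 by 4.31. The other probe sets of CTLA4 differed by -0.28 to -1.45, 1 of them at nearly the same mean signal. All 8 ALDH+ arrays lay below the ALDH- median for each of these genes.

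The T and NK cell list fell as a group, with a median log2 difference of -4.08 and all 16 measured members below 0. Of these, 14 passed over all genes and 16 when adjusted over the list alone. The camera test of limma gave an adjusted p of 2e-23, and the adjusted p = 0.248 with an estimated correlation. The list score was -1.87 ± 0.32 in ALDH+ and 1.87 ± 1.98 in ALDH- arrays (SD, n = 8 each; two-sided exact permutation p = 0.000466, adjusted 0.00932). Within batches C, D and E the score differed by -2.0, -3.55 and -4.90. With batch as a block the median was -4.29, with an adjusted p of 1.69e-22 in camera and 0.123 in fry. The ALDH- arrays varied widely, and ALDH- replicate 1 scored -1.73, inside the range of the ALDH+ arrays. That array also lay inside their range for the aldehyde dehydrogenase score (0.51) and the first principal component (-50.8), but above it for the B and plasma cell score (0.76) and the endothelial score (2.24).

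B and plasma cell genes fell too. IGHM, the heavy chain of IgM, was lower by a log2 difference of -4.62 (SE 0.95, limma adjusted p = 0.0231). The antibody light chain gene IGKC was lower by -2.40 and POU2AF1, a B cell coactivator, by -4.19, with limma adjusted p of 0.0313 and 0.0491. MS4A1, which encodes CD20, had a difference of -4.49 that missed the threshold (limma adjusted p = 0.0641). The list had a median of -2.0, with 3 of 11 members past the threshold over all genes and 9 when adjusted over the list alone. Its camera adjusted p was 1.05e-08 in limma, and the adjusted p = 0.280 with an estimated correlation. The score differed by -4.27, -2.66 and -1.20 within batches C, D and E, and the two-sided exact permutation p was 0.000622 (adjusted 0.00932). The groups overlapped: ALDH- replicates 4 and 8 scored -0.65 and -0.54, below ALDH+ replicate 5 at -0.33. The call for IGHM was lost without ALDH+ replicate 8, at a limma adjusted p of 0.0523, and those for IGKC and POU2AF1 held in 7 and 4 of the 16 fits with an array left out.

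**Figure D1:**
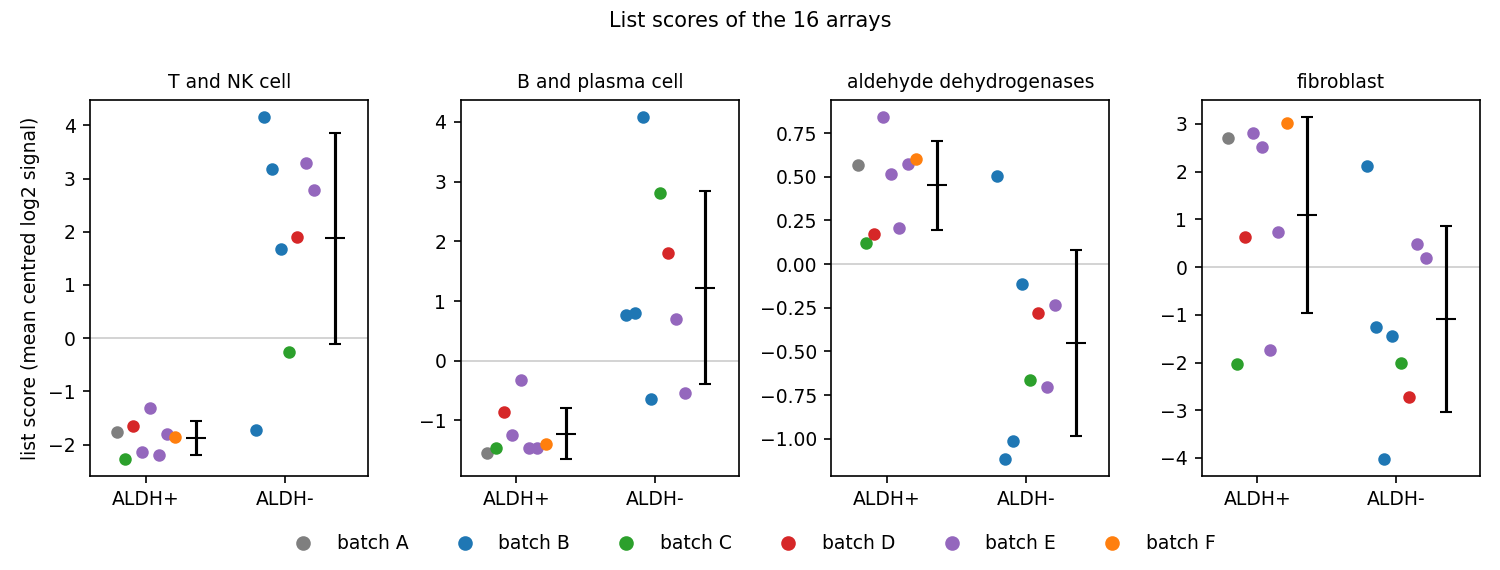
Scores of 4 gene lists on each of the 16 arrays (vertical axis, mean of the members' log2 values after centring each gene), by group, with points coloured by array batch and bars giving mean and SD over 8 arrays. T and NK cell scores averaged -1.87 in ALDH+ and 1.87 in ALDH- arrays, with ALDH- replicate 1 inside the ALDH+ range. Scores of the groups overlapped in the other lists shown too.

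Aldehyde dehydrogenase genes were higher in ALDH+ cells. ALDH1A1 and ALDH1A3, which oxidise retinaldehyde to retinoic acid, averaged 8.30 ± 1.97 and 9.25 ± 1.53 in ALDH+ arrays against 5.14 ± 0.76 and 6.30 ± 1.29 in ALDH- arrays (SD, n = 8 each). The rises were 8.96-fold and 7.73-fold, with limma adjusted p of 0.0296 and 0.0327. The ALDH- mean of ALDH1A1 lay below the filter value of 5.82, where signals are compressed, so its fold is rough. Both are among the 12 largest rises, each of which passed in 3 to 10 of the 16 fits with an array left out. ALDH1A2, of the same family, differed by 2.33 and ALDH1L2, a mitochondrial folate enzyme, by 2.14. These last passed only when adjusted over the list alone, where 4 of 18 members did, against 2 of 18 over all genes. The list had a median of 0.52 with 15 members above 0 (camera adjusted p = 0.00363 in limma, adjusted p = 0.346 with an estimated correlation). Its score was 0.45 ± 0.25 in ALDH+ and -0.45 ± 0.53 in ALDH- arrays (SD, n = 8 each; two-sided exact permutation p = 0.00109, adjusted 0.0109). Within batches C, D and E the score differed by 0.78, 0.45 and 1.00. With batch as a block ALDH1A1 differed by 2.45 and ALDH1A3 by 2.38, and limma's adjusted p rose to 0.418 and 0.508. The T and NK cell and fibroblast lists moved by medians of -4.08 and 2.09 between the same arrays.

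Genes of retinoid handling and response rose as a list, with 13 of 14 members above 0 and a median of 0.69. The camera adjusted p was 0.000882 in limma, and the adjusted p = 0.315 with an estimated correlation. The score difference had a two-sided exact permutation p of 0.00202 (adjusted 0.0152) and was 0.90, 0.56 and 0.84 within batches C, D and E. No single member passed over all genes or adjusted over the list alone. The largest difference among the named members was 3.48 for RARRES1, a retinoid-induced gene, with a limma adjusted p of 0.0955. RARRES2 differed by 2.45, the retinaldehyde reductase DHRS3 by 1.31 and the transglutaminase TGM2 by 1.15. The T and NK cell and fibroblast lists moved by medians of -4.08 and 2.09 between the same arrays.

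By the probe set used for each gene, the largest rise was that of AOX1, an aldehyde oxidase, at 12.6-fold (log2 difference 3.66, SE 0.90, limma adjusted p = 0.0492). Its other probe set, with a mean signal of 6.67 against 6.96, differed by 1.58. GULP1, an engulfment adaptor, rose 10.1-fold and ROBO1, an axon guidance receptor, 8.54-fold. The metalloreductases STEAP2 and STEAP4 rose 8.05-fold and 7.07-fold, and the protocadherins PCDHB16 and PCDHB14 rose 8.33-fold and 6.93-fold. AHNAK2 rose 6.52-fold, LARP6, which binds collagen mRNA, 6.17-fold, and CACHD1 6.11-fold, where the other probe set of CACHD1 differed by 0.02. The ALDH- means of AOX1, GULP1, ALDH1A1, PCDHB16, PCDHB14 and CACHD1 were 5.13, 5.48, 5.14, 4.50, 4.84 and 5.37, below the filter value of 5.82. Low signals are compressed, so the folds of these genes and the order of the rises are rough. Other large falls were PLAC8 at -4.91, with the smallest adjusted p of all genes (limma 0.00022), and the receptor P2RY10 at -4.67. Of the 12 largest falls, all but TRBC1 and IGHM had an ALDH+ mean below the filter value. The sizes and order of the falls are therefore rough too. Protocadherin beta genes share similar sequence, and the probe sets of TRBC1, CD24, IGKC and CDH11 used here are of a type that can cross-hybridise. These values can therefore mix related transcripts.

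**Figure D2:**
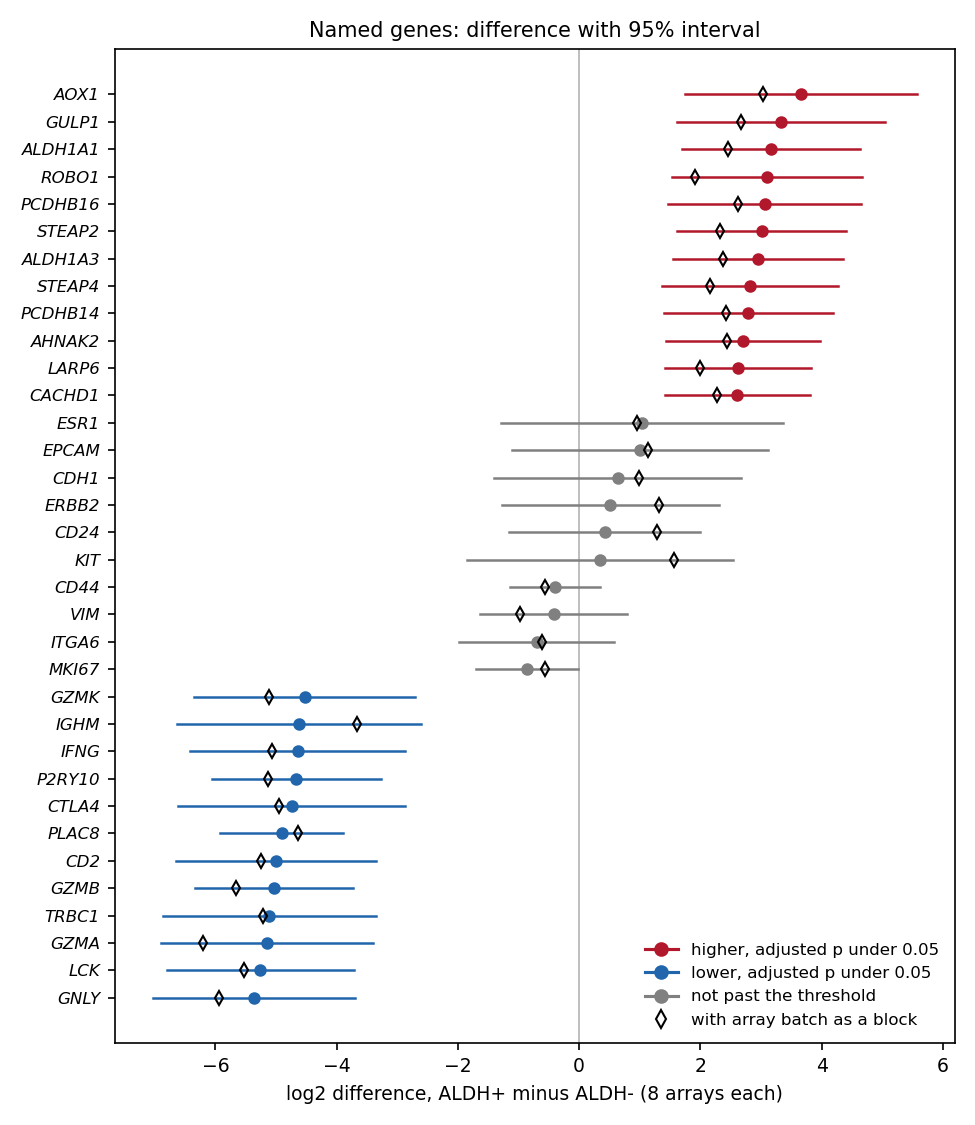
Log2 difference of ALDH+ minus ALDH- cells (horizontal axis, 8 arrays per group) for the 12 largest rises, the 12 largest falls and the genes always reported, with 95% intervals of limma as lines and the value with array batch as a block as open diamonds. The falls lie between -4.53 and -5.37 and the rises between 2.61 and 3.66. The diamonds rest on the 6 ALDH+ and 4 ALDH- arrays of the batches that hold both groups.

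Fibroblast genes were higher in ALDH+ arrays as a list but not one by one. All 16 measured members lay above 0 with a median log2 difference of 2.09, and none passed over all genes or adjusted over the list alone. PDGFRA, a growth factor receptor of fibroblasts, differed by 3.34 (SE 1.22, limma adjusted p = 0.169). SFRP2, FBLN1 and CDH11 differed by 3.04, 2.65 and 2.92. The collagens COL1A2 and COL3A1 were abundant in both groups, at 13.64 and 13.80 in ALDH+ against 11.82 and 12.22 in ALDH- arrays. The camera adjusted p was 3.03e-06 in limma, and the adjusted p = 0.648 with an estimated correlation. The score differed by -0.02, 3.37 and 0.75 within batches C, D and E, and with batch as a block the median was 0.95 and the camera adjusted p 0.0510. The two-sided exact permutation p of the score was 0.0463, or 0.139 when adjusted over the lists.

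The Wnt, Hedgehog and mesenchymal transition lists were also higher in camera. The Wnt pathway and targets had a median of 0.93 and the Hedgehog pathway 0.77, with limma camera adjusted p of 0.00855 and 0.0120. Mesenchymal transition had a median of 1.33 and an adjusted p of 0.0442. Each call was lost with an estimated correlation, at adjusted p = 0.643, 0.643 and 0.775 with an estimated correlation. Each was also lost with batch as a block, where the medians of the Wnt and Hedgehog lists were 0.53 and 0.45. The camera direction of mesenchymal transition turned to lower there, with its median at 0.11, and its call held in 8 of the 16 fits with an array left out. The Wnt receptor FZD7 differed by 2.35 and SNAI2, a transcription factor of mesenchymal transition, by 2.69, with limma adjusted p of 0.0865 and 0.156. The Hedgehog co-receptors CDON, GAS1 and BOC differed by 2.40, 2.93 and 2.55, and these 3 of 10 members passed only when adjusted over the list alone. The fibroblast list shares 4 of its 16 genes with other lists. Within batches C, D and E the scores differed by 0.87, 0.73 and 0.57 for the Wnt list, 0.64, 1.03 and 0.83 for Hedgehog, and 0.01, 1.30 and -0.19 for mesenchymal transition. The T and NK cell and fibroblast lists moved by medians of -4.08 and 2.09 between the same arrays.

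The luminal progenitor list was higher in camera, with all 15 members above 0 and a median of 0.93. ALDH1A3 was its 1 member past the threshold, over all genes and adjusted over the list alone. The keratin KRT23 differed by 1.88, the protease inhibitor SLPI by 0.93 and the folate receptor FOLR1 by 0.51. The camera adjusted p was 0.00684 in limma, and the adjusted p = 0.593 with an estimated correlation. The fry adjusted p was 0.104, and the two-sided exact permutation p of the score was 0.0398 (adjusted 0.139). The score differed by 1.25, 1.02 and 0.81 within batches C, D and E. Between the same arrays the T and NK cell list moved by -4.08 and the fibroblast list by 2.09 (medians).

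Cell cycle genes fell as a list in camera. All 27 members lay below 0 with a median of -0.76, and none passed over all genes or adjusted over the list alone. MCM5, a replication helicase subunit, differed by -1.35 and the mitotic kinase PLK1 by -0.59. MKI67, the proliferation marker, differed by -0.86 (SE 0.40, limma adjusted p = 0.275). The camera adjusted p was 1.49e-05 in limma, and the adjusted p = 0.723 with an estimated correlation. The score differed by 1.03, -0.15 and -0.98 within batches C, D and E, so its direction differed between batches. With batch as a block the median was -0.27 and the list passed camera as lower (adjusted p = 0.0111). The two-sided exact permutation p of the score was 0.136. The T and NK cell and fibroblast lists moved by medians of -4.08 and 2.09 between the same arrays.

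The interferon response list had a median of -0.50 and cytosolic ribosomal proteins -0.15, with limma camera adjusted p of 0.0300 and 0.0161. Both calls were lost with an estimated correlation, at adjusted p = 0.775 and 0.731 with an estimated correlation. With batch as a block both lists passed camera as lower (adjusted p = 0.00133 and 0.0250). The permutation of the scores within batches gave p = 0.317 and 0.267 (adjusted 0.559 and 0.531). ISG20, an interferon-induced exonuclease, fell by 2.14 on the log2 scale and was the 1 interferon member past the threshold, over all genes and adjusted over the list alone (limma adjusted p = 0.0483). IFI27 went the other way at 1.95, without passing. RPS3, of the ribosomal list, differed by -0.58. Within batches C, D and E the interferon score differed by -0.85, 0.16 and -0.98 and the ribosomal score by -0.12, -0.19 and -0.07. The interferon call was lost in turn without ALDH- replicates 1, 3, 6 and 8 and without ALDH+ replicates 2, 5 and 6, with adjusted p up to 0.219. The ribosomal call was lost without ALDH- replicates 2 and 7 and without ALDH+ replicates 2 and 3, with adjusted p up to 0.0850, and that of ISG20 held in 3 of the 16 such fits. The T and NK cell and fibroblast lists moved by medians of -4.08 and 2.09 between the same arrays.

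In the lists that did not pass, single genes fell. CXCR4, a chemokine receptor placed among the stem cell markers and abundant on lymphocytes, fell by 2.03 on the log2 scale (limma adjusted p = 0.0111). DUSP2, a phosphatase induced in activated lymphocytes, fell by 2.10, and MFNG, a Notch-modifying enzyme, by 2.29, with limma adjusted p of 0.0108 and 0.0296. Each was the 1 member of its list past the threshold, over all genes and adjusted over the list alone. The stem cell marker list had a median of 0.42, the Notch list -0.04 and the immediate early list -0.17, with limma camera adjusted p of 0.615, 0.615 and 0.126. With batch as a block the immediate early list passed camera as lower, at a median of -0.24 and an adjusted p of 0.00941. Its score differed by -0.82, 0.41 and -0.31 within batches C, D and E. A permutation of the group labels within batches gave p = 0.283 for that score (adjusted 0.531). The MFNG call held in 11 of the 16 fits with an array left out, and those of CXCR4 and DUSP2 in all 16.

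The usual markers of breast tumour-initiating and epithelial cells did not pass the threshold. CD44 differed by -0.40 (SE 0.35, limma adjusted p = 0.617) and CD24 by 0.42 (SE 0.74, limma adjusted p = 0.834), and probe sets of CD24 differed in sign. Other probe sets of CD44 with a mean signal above 8 differed by -0.36 to -1.36. EPCAM, CDH1 and ITGA6 differed by 1.01, 0.63 and -0.70, and VIM by -0.42. ESR1, ERBB2 and KIT differed by 1.03, 0.51 and 0.34, with SE of 1.10, 0.84 and 1.04. Epithelial genes as a list had a median of 0.52 and a limma camera adjusted p of 0.384, and 0.00545 with batch as a block, where the median was 1.00. The score of that list differed by 1.99, 0.59 and 0.75 within batches C, D and E. A permutation of the group labels within batches gave p = 0.133 for that score (adjusted 0.40). The hormone-sensing luminal list had a median of 0.47 and the basal list 0.81, with adjusted p of 0.552 and 0.0631. In the 16 fits with an array left out the hormone-sensing median ran from -0.18 to 0.83, and the basal list passed in 4.

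Among the other cell type lists, macrophage genes had a median of -0.04 and endothelial genes -0.57, with limma camera adjusted p of 0.569 and 0.0686. With batch as a block macrophage genes passed as lower, at a median of -1.30 and an adjusted p of 0.000179, and their score differed by -0.88, 1.06 and -2.40 within batches C, D and E. A permutation of the group labels within batches gave p = 0.217 for that score (adjusted 0.50). Mast cell, erythrocyte and adipocyte lists had medians of 1.18, -0.01 and 0.19 and limma adjusted p of 0.523, 0.454 and 0.642. Antioxidant genes had a median of 0.29 and just missed the threshold (limma adjusted p = 0.0507), and they passed in 10 of the 16 fits with an array left out. The NADPH-dependent reductases AKR1C1, AKR1C2 and AKR1C3 in that list differed by 2.54, 2.46 and 2.24, and their near-identical sequences can share probes. Oxidative phosphorylation and ABC transporters had medians of 0.15 and 0.25, with limma adjusted p of 0.20 and 0.632. Hypoxia and glycolysis, lipid synthesis and the unfolded protein response had medians of 0.00, -0.03 and -0.12, with adjusted p of 0.872, 0.882 and 0.552. The NF-kB list had a median of 0.19 while its camera direction was lower, with an adjusted p of 0.642.

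**Figure D3:**
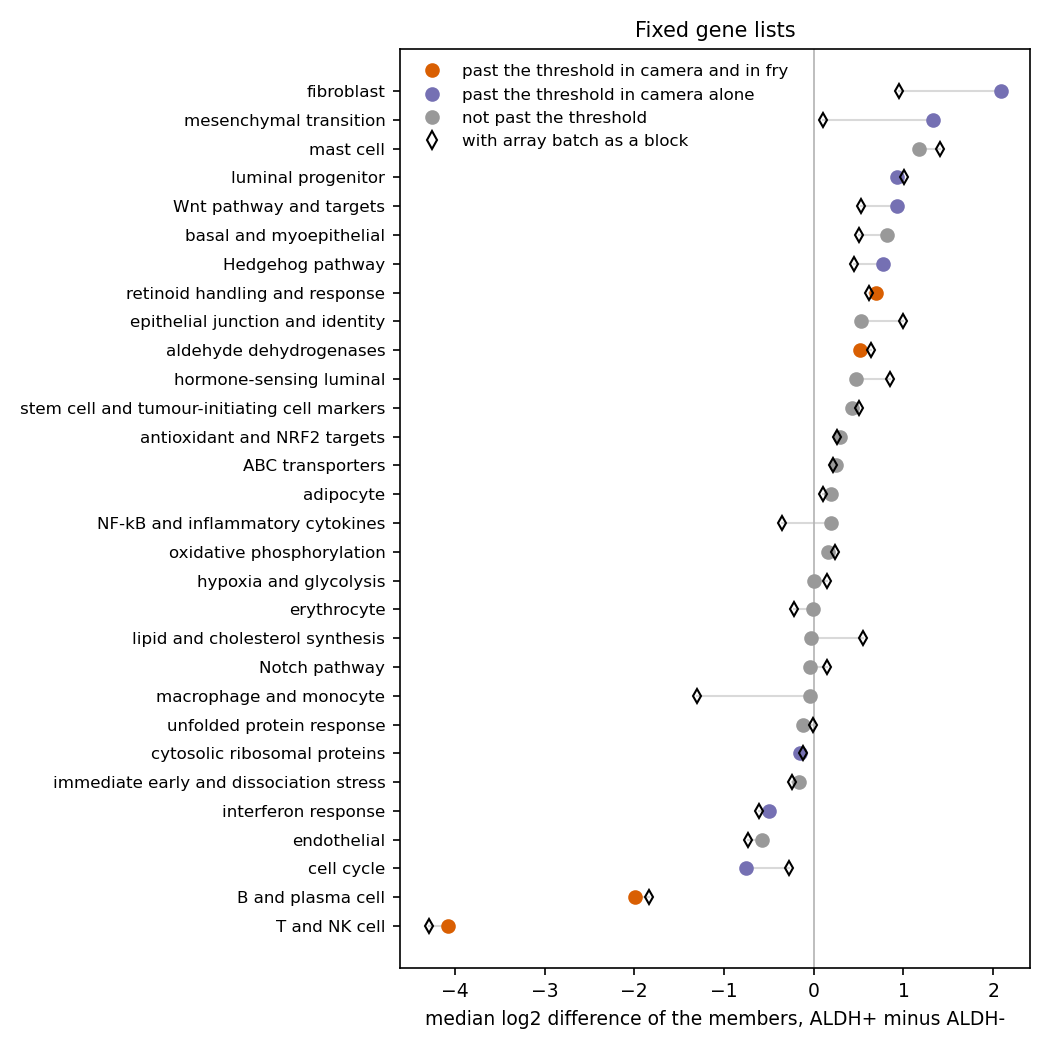
Median log2 difference of the members of each of the 30 lists (horizontal axis, ALDH+ minus ALDH-), with filled points for the fit without batch, coloured by the tests they passed, and open diamonds with array batch as a block. T and NK cell genes stand at -4.08 and fibroblast genes at 2.09, and mesenchymal transition moves from 1.33 to 0.11.

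Of 13163 genes, 51 were higher and 194 lower in ALDH+ cells (limma, Benjamini-Hochberg). At an unadjusted p under 0.05 there were 1269 higher and 983 lower. Of the 30 lists, 12 passed in camera, 7 higher and 5 lower. The aldehyde dehydrogenase, retinoid, T and NK cell and B and plasma cell lists were the 4 that also passed in fry and in the exact permutation test of the score. With an estimated correlation 0 lists passed camera, and 4 had an unadjusted p under 0.05. With batch as a fixed block 8 of the 12 lists passed camera in the same direction. The Wnt, Hedgehog, mesenchymal transition and fibroblast lists did not. In the permutation of the scores within batches no list passed when adjusted over the lists, where the lowest adjusted p was 0.25. In 21 lists no member passed over all genes or adjusted over the list alone.

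With array batch as a fixed block limma called 0 genes in either direction, with 466 higher and 638 lower at an unadjusted p under 0.05 and a smallest adjusted p of 0.0636. All 245 genes kept their sign in that fit, the median of the 51 higher genes moved from 2.08 to 1.85 and that of the 194 lower genes from -2.70 to -2.88. As a random block batch left 33 higher and 162 lower genes. In only the batches with both groups, with batch as a block, 6 genes were higher and 96 lower. The differences in that fit are those of the fixed block over all arrays, and only the variance estimate is another. Within batches C, D and E 48, 50 and 51 of the 51 higher genes and 189, 193 and 194 of the 194 lower genes kept their sign. These genes were called on the same arrays, so the agreement of sign is partly fixed by that choice. It is no separate test of batch. Without ALDH- replicate 1 the counts were 207 higher and 340 lower. Higher genes numbered 6 and 8 without ALDH- replicates 2 and 3, 15, 32 and 19 without ALDH- replicates 5, 7 and 8, 23, 17, 15 and 9 without ALDH+ replicates 1, 4, 5 and 8, and 87 and 85 without ALDH+ replicates 2 and 3. Lower genes numbered 98 and 90 without ALDH- replicates 2 and 3, 116 and 113 without ALDH- replicates 7 and 8, and 113 and 85 without ALDH+ replicates 5 and 8. Without the 2 arrays that stood apart on the principal components there were 14 higher and 52 lower genes. Of the 12 largest falls 11 passed with each array left out in turn, whereas each of the 12 largest rises passed in 3 to 10 of the 16 such fits. Single arrays stood far from the rest of their group for PCDHB14, AHNAK2, GNLY, IGHM, ERBB2, ALDH1L2, GAS1 and KRT23.

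The measure of RNA quality differed between the groups by less than the spread between arrays. The log2 signal at the 3 prime end minus that at the 5 prime end, averaged over ACTB and GAPDH, was 2.82 ± 0.49 in ALDH+ and 2.80 ± 0.68 in ALDH- arrays (SD, n = 8 each). The difference of 0.02 had a two-sided exact permutation p of 0.940. Within batches it was 0.04.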

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

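The tests of array batch and RNA quality on the T and NK cell genes and of fewer lymphocytes on the fibroblast genes were chosen after the results they bear on were seen. The other tests and the random splits were set before theirs.

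T and NK cell genes were lower in ALDH+ arrays at a median of -4.08. The data argue against RNA quality, as read from the 3 prime minus 5 prime signal, as the whole cause: its slope with the score within groups times its difference of 0.02 between groups carried at most 34.6% of the score difference over the 95% t intervals of both. Array batch stays open in part. The score difference within batches was 106% of the pooled one (95% t interval -6.39 to -1.59, so at least 42.3%). With batch as a block the list passed camera (adjusted p = 1.69e-22), but not fry (adjusted p = 0.123) or camera with an estimated correlation (adjusted p = 0.473). The permutation within batches gave p = 0.0167, the lowest that 60 exchanges allow. Adjusted over the lists it was 0.25 and did not pass. The tests of RNA quality and batch are the last of several forms, set after earlier ones with either outcome had been run. The first batch test was one on the smallest difference within a batch, -2.0, which missed a bound of -2 by less than rounding shows. Lymphocytes in the ALDH- fraction may account for the pattern: the abundant IL7R and TRBC1 fell from 11.11 and 11.57 to 6.86 and 6.46, no gene of the first list stands in another list, and the labels used here name no gate that would remove blood cells. A second T cell list fixed before its values were read had a median of -3.19 with 27 of 27 members lower. It reads genes of the same cell type on the same arrays, so it repeats the pattern and cannot tell lymphocytes from another cause.

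Fibroblast genes were higher in ALDH+ arrays at a median of 2.09. Fewer lymphocytes would raise markers of other cell types alike only if the sort left those types otherwise unchanged. The fibroblast score difference exceeded that of macrophages by 2.29 (95% bootstrap interval over arrays 0.689 to 4.05) and that of endothelium by 2.63 (1.34 to 3.92). Macrophage genes were lower with batch as a block, at a median of -1.30, and no other measure of these types was at hand. The gaps therefore cannot decide whether fewer lymphocytes share in the rise. Fibroblasts in the ALDH+ fraction may contribute, and the most abundant genes COL3A1 and COL1A2 were at 13.80 and 13.64 in ALDH+ arrays. A second fibroblast list had a median of 2.24 with 26 of 26 members higher, none of them past the threshold alone. It reads genes of the same cell type on the same arrays, so it repeats the pattern and cannot tell fibroblasts from another cause. Tumour cells with a mesenchymal programme express the same genes and were not tested apart. Array batch cannot be told apart from the group here, because the difference was -0.024 in batch C, 3.37 in batch D and 0.75 in batch E, with 1 array per group in C and D. The permutation of the score within batches gave p = 0.367 (adjusted 0.60).

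Cell cycle genes lay lower in ALDH+ arrays at a median of -0.76. Array batch cannot be told apart from the group, because the score differed by 1.03 in batch C, -0.15 in batch D and -0.98 in batch E. With batch as a block the list passed camera as lower (adjusted p = 0.0111), but the permutation of the score within batches gave p = 0.50 (adjusted 0.62). Dividing lymphocytes in the ALDH- fraction also stay open as a possible explanation, with a Pearson r of -0.0895 between the cell cycle and T and NK cell scores over the 8 ALDH- arrays (permutation p = 0.833, adjusted 0.833; Spearman rho -0.24, permutation p = 0.582, adjusted 0.582) and -0.23 without the 2 farthest arrays. A biological difference in division between the sorted fractions was not tested.

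Other splits of the 16 arrays bear on the counts. As many higher genes as the real 51 came from 3 of 100 splits and as many lower genes as the real 194 from 2 of 100, the real one included. Counts this large were thus rare among splits drawn without regard to batch, from 6435 possible ones. Splits that keep the batches were not run for the gene counts, so chance is not excluded. With batch as a fixed block over all 16 arrays limma called 0 genes, with 466 higher and 638 lower at an unadjusted p under 0.05. With batch as a block in only the batches with both groups, it called 6 higher and 96 lower genes. Both fits take the group difference from the batches with both groups and differ only in the variance estimate. Each split counts by its larger direction, which reached 734 genes in the highest other split. That split called 849 genes in all, which points to a structure of the samples: it put 6 of the 8 ALDH+ arrays together, and its sides differed by 3.28 in the fibroblast score. The aldehyde dehydrogenase score differed by 0.92 between its sides, against 0.90 between the real groups. Wnt and Hedgehog scores differed by 1.44 and 1.37, against 1.03 and 1.09. For the T and NK cell score the split gave less, -2.64 against -3.75. No gene was called in 95 splits. For the 12 lists chance could not be excluded, because 25 of 100 splits gave as many lists past the threshold in camera and the highest gave 17.

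Single arrays stood far from the other arrays of their group in 11 of 224 sets of values tested, where chance alone gives about 11.2. ALDH- replicate 1 read 4.53 for GNLY, against a next value of 9.11, and 9.70 for AHNAK2 and 7.54 for ALDH1L2, the highest ALDH- values of both. Without that array the counts were 207 higher and 340 lower genes, and a wrong label for it stays open. Against one stands its B and plasma cell score of 0.76, above the highest ALDH+ array at -0.33. ALDH+ replicate 3 read 4.32 for PCDHB14, the lowest ALDH+ value, and 13.21 for ERBB2, the highest, with the next array at 9.71. ALDH+ replicate 5 read 10.87 for IGHM, against a next value of 7.14. ALDH+ replicate 6 read 6.91 for GAS1, the lowest, and 9.65 for CYP27A1, the highest. ALDH+ replicate 8 read 4.33 for KRT23, the lowest ALDH+ value. ALDH- replicate 5 read 8.05 for RFC5, the lowest ALDH- value. ALDH- replicate 2 had a score of -0.68 for the ABC transporters, with the next array at -0.08.

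Probe sets without a listed gene also differed between the groups. Of 3286 such probe sets tested, 5 were higher and 22 lower in ALDH+ arrays (limma, Benjamini-Hochberg over all probe sets tested), and their genes stay unnamed here.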

How the results depend on the processing

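The fits with the T and NK cell score as covariate and without 2 arrays that stood apart were chosen after the data were seen. The counts of 51 higher and 194 lower genes stayed within 1.5 times under quantile normalization, median centring, the mean of a gene's probe sets, every probe set on its own, the trended and robust prior, the RNA quality covariate and a log2 difference of at least 1. The count of 12 lists stayed at 11 to 13 in these fits, except for every probe set and the log2 difference, where lists were not tested. Higher genes numbered 25 with no filter, 33 with batch as a random block, 22 without the batch of ALDH- arrays only and 380 with array weights. Higher and lower genes numbered 17 and 99 with the filter at the 75th percentile and 202 and 352 at an adjusted p below 0.10. They numbered 14 and 52 without the 2 arrays that stood apart. In only the batches with both groups, with batch as a block, they numbered 6 and 96. Of these, 3 and 84 were also called over all arrays without batch. Both counts were 0 with batch as a fixed block in limma, where residual degrees of freedom fell from 14 to 9. None of the 245 genes called without batch changed sign there, but they were called on these same arrays. Both counts were also 0 with the T and NK cell score, with 104 higher and 139 lower at an unadjusted p under 0.05. That score nearly separates the groups by itself, and 7 lists passed there. The filter, the thresholds and the smaller sets of arrays change what is tested by their construction, and for the other counts the cause was not tested. Leaving out each array in turn gave 6 to 207 higher genes, 85 to 340 lower genes and 10 to 14 lists. Lists passing numbered 0 in camera with an estimated correlation, where 4 had an unadjusted p under 0.05, and 4 in fry. The replicate block left 37 higher and 68 lower genes, 16 and 64 of them shared with the fit without it. Arrays of the same number correlated at -0.25 to 0.16 after group means were removed, and no ALDH+ array correlated best with its own number, so the numbers do not pair the arrays. ALDH+ replicates 2, 3, 5 and 7 correlated best with ALDH- replicates 5, 6, 7 and 8 of their own batch, at 0.48, 0.67, 0.46 and 0.44. ALDH+ replicates 1, 4, 6 and 8 correlated best with an array of another batch. A pairing within batches stays possible, and the main fit treats the arrays as unpaired. Mesenchymal transition turned lower in camera at a median of 0.11 with batch as a fixed block and in batches with both groups, and lipid synthesis turned higher there at 0.55. With the T and NK cell score the direction turned for epithelial genes (-1.03), NF-kB genes (0.67), the unfolded protein response (0.39) and ribosomal proteins (0.073), and the cause was not tested. It also turned for the T and NK cell list (0.21) and its members GZMK (0.20) and IL7R (0.23), which says nothing, since the covariate is the mean of that list. The RNA quality difference kept its side of the threshold in every alternative, at -0.11 with ACTB alone, 0.15 with GAPDH alone and -0.11 to 0.22 with each array left out. Across all alternatives, named genes stayed on the same side of the threshold in 4302 cases, 61 of which changed sign without passing on either side. They lost the call in 402, gained it in 33 and reversed in 2. Lists stayed on the same side in 875 cases, 41 of which changed sign in that way. They lost the call in 59, gained it in 41 and reversed in 8. Signals near the array's background limit what these values show of genes with low expression.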

Other observations

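The genes in the first paragraph were chosen after their values were seen, as those with the smallest p among genes not yet named. The tests of ALDH1A1, ALDH1A3 and the protocadherin genes were written before their results were seen.

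Further genes rose in ALDH+ cells. SEC22B, a vesicle fusion protein of the secretory pathway, was 11.57 ± 0.11 in ALDH+ and 10.74 ± 0.22 in ALDH- arrays (SD, n = 8 each), a log2 difference of 0.84 (SE 0.13, limma adjusted p = 0.00654). CYP27A1 and CYP7B1, enzymes that hydroxylate sterols on the acidic route to bile acids, rose by 1.11 and 2.45, with limma adjusted p of 0.00942 and 0.0208. RFC5, a subunit of the clamp loader of DNA replication, rose by 0.95 (limma adjusted p = 0.0115). All 8 ALDH+ arrays lay above the ALDH- median for these 4 genes, and each passed in all 16 fits with an array left out. With batch as a block the differences were 0.74, 1.08, 1.90 and 1.00 for SEC22B, CYP27A1, CYP7B1 and RFC5. The thyroid hormone receptor THRB, the cell cycle inhibitor CDKN2B and the cytokine receptor LIFR rose by 2.16, 2.38 and 2.23, and LGR4, a receptor that amplifies Wnt signals, by 2.15, and these passed in 11, 13, 6 and 2 of those 16 fits. Among the falls, the costimulatory receptor CD27, the shared cytokine receptor chain IL2RG and lymphotoxin beta (LTB) differed by -3.66, -3.40 and -3.60.

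A hypothesis was that ALDH1A1 signal follows the fibroblast content of the ALDH+ fraction. Over the 8 ALDH+ arrays ALDH1A1 and the fibroblast score had a Pearson r of 0.893 (permutation p = 0.00233, adjusted over 6 relations 0.0140) and a Spearman rho of 0.952 (permutation p = 0.00114, adjusted 0.00685), with r at 0.911 without the 2 farthest arrays. Stromal or mesenchymal-like cells with aldehyde dehydrogenase activity may therefore share in the ALDH1A1 rise. Another hypothesis was that ALDH1A3 follows the epithelial score, which the data went against: r was -0.865 (permutation p = 0.0216, adjusted 0.0260; rho -0.762, permutation p = 0.0368, adjusted 0.0735). ALDH1A1 and ALDH1A3 were not high in different ALDH+ arrays either, with r = 0.823 (permutation p = 0.0161, adjusted 0.0242; rho 0.690, permutation p = 0.0694, adjusted 0.0833) and 0.915 without the 2 farthest. ALDH1A3 also went with the fibroblast score, at r = 0.895 (permutation p = 0.0063, adjusted 0.0189; rho 0.690, permutation p = 0.0694, adjusted 0.0833), and ALDH1A1 against the epithelial score, at r = -0.810 (permutation p = 0.0134, adjusted 0.0242; rho -0.857). The fibroblast and epithelial scores themselves ran largely in opposite directions over these arrays. They were 3.03 and -2.22 in ALDH+ replicate 8 and -2.04 and 1.25 in ALDH+ replicate 2. The relations above therefore overlap and are not separate tests. Only batch E held more than 1 ALDH+ array, and its 4 are too few for a correlation within a batch.

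Because 2 protocadherin beta genes stood among the 12 largest rises, the other 13 genes of that cluster with a probe set were tested as a set. Of these 12 were higher in ALDH+ arrays, with a median log2 difference of 0.55 and a two-sided exact permutation p of 0.00855 for their mean score. Within batches C, D and E the score differed by 1.57, -0.12 and 1.14. Shared sequence among these neighbouring genes may carry signal of 1 gene to the probe sets of others, which these values cannot separate.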
